A study of Homo sapiens with 6 samples.

How the data were processed

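RNA of sorted GFP-negative cells from co-cultures of MNT-1 melanoma cells with HaCaT keratinocytes was measured in 6 libraries. Per the labels' protocols, MNT-1 cells at 20000 per ml had 24 h on their own before HaCaT cells carrying lentivirus joined them at 40000 per ml, and the co-culture in high-glucose medium with 20% serum was collected after 72 h. Libraries were made from poly-T selected mRNA with random-hexamer priming and read as 150 bp pairs on a NovaSeq instrument, per the labels' protocols. The labels put 3 libraries in the non-targeting group and 3 in the KRT5-knockdown group.

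The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and GATK 3.7, and the mouse build mm10. All 1130 gene identifiers are human Ensembl identifiers and matched GENCODE release 29, and the start and end of 1129 of them equal those of that annotation, so coordinates are given as GRCh38. The build used for alignment, the strand setting of the counting and the differential expression tool are not given in the sources used here. The deposited per-library values are a signal unit, gene read counts that the authors divided by a size factor per library, called normalized counts here. Every value in each library was a whole multiple of the smallest value above 0 of that library (tolerance 1e-06), with implied size factors between 0.941 and 1.036 if that value is 1 read. For knockdown library 1 the step was close to 1 (implied size factor 1.008), and its values were whole multiples of that step as well. That the step is 1 read is assumed for all 6 libraries. The authors also deposited a group mean, a log2 fold change of knockdown over control, a p-value and an adjusted p-value for each gene.

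The table holds only genes whose deposited p-value was below 0.05 (highest 0.0499). From the deposited p-values and adjusted p-values, the adjustment covered 16311 genes, and Benjamini-Hochberg values recomputed with that number equalled the deposited ones (relative tolerance 1e-06) for 1004 of the 1023 listed genes with an adjusted p below 1. The 19 that differed have the highest p-values of the 1023 and share a deposited adjusted p of 0.789, a value that the procedure can take from genes outside the table. These 1023 genes are 6.27% of 16311, where chance gives 816. The other 107 listed genes, with a mean of at most 7.40 normalized counts, have an adjusted p of 1. Because genes were selected on the same comparison, no new test across genes was used for the calls, as fixed before the data were examined for a filtered table. A gene was called where the deposited adjusted p was below 0.05. Means and SDs were computed from the per-library values, and the log2 ratio of these means differed from the deposited log2 fold change by at most 0.0096 for the called genes. No test on read counts was run.

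Genes were named by a fixed rule that took KRT5, up to 8 called genes per direction with the largest fold change among protein-coding genes with a mean of at least 50 normalized counts in the higher group and no overlap between the groups, the 4 called genes per direction with the smallest adjusted p, and called members of the gene lists. The rule named 12 genes, and every other gene was named after its values were seen, because all 33 called genes are given or because it is a listed member of a gene list. The 16 gene lists, also fixed beforehand, cover pigmentation, keratinocyte markers, Notch, Wnt, melanogenic signalling, dedifferentiated melanoma, proliferation, interferon response, inflammation, endoplasmic-reticulum and amino-acid stress, hypoxia and glycolysis, sterol and lipid synthesis, matrix and adhesion, early response, lysosome and autophagy, and respiratory chain with ribosome. For each list the listed members with higher and lower values were set against all other listed genes with a two-sided Fisher's exact test, adjusted over the 16 lists. That test compares the balance of directions and gives no enrichment, and it treats genes as independent, which they are not. With 2000 families of random lists of the same sizes, 0.95% had a list past an adjusted p of 0.05. Random draws hold no sets of genes that move together, so this share does not cover lists of co-regulated genes. For the count adjusted over the list alone, the Benjamini-Hochberg correction used the full number of genes in the list.

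A descriptive test used limma 3.58.1 in R 4.3.3 on log2(normalized count + 1) of the listed genes, with a mean-variance trend and adjustment over 16311 genes. Because these genes were selected on the same libraries, its adjusted p-values are not valid as calls. The pseudocount pulls its fold changes of low genes towards 0, while a difference of mean logs can also lie further from 0 than the log of the ratio of means. On simulated counts for 1130 genes with a dispersion of 0.01, it recovered 82.1% of genes changed 1.5-fold and 100% of those changed 2-fold and 4-fold, and called 0.86% of unchanged genes, when adjusted over the 1130 genes. Adjusted over 16311 genes, as for the data, it recovered 61.2%, 94.0% and 100%. On the data it called 3 genes, although 22 of the 33 called genes have an absolute log2 fold change of at least 1, so the simulated recovery does not carry over to these libraries. Alternatives were pseudocounts of 0.5 and 5, minimum means of 10 and 50 normalized counts, an adjusted p of 0.01, an absolute log2 fold change of at least 1, leaving out the keratinocyte list, leaving out each library and a replicate block. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

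Several steps can affect the values. The selection on p makes the fold changes of listed genes larger on average than in a new experiment, most of all for low genes. Genes outside the table were not analysed here. Counting error is largest for genes with few normalized counts, such as CEACAM5 in the knockdown libraries. The sorted fraction probably holds keratinocyte RNA, since KRT5 was targeted in the keratinocytes and fell in this fraction to 8.49% of control. The gene counts cannot separate such RNA from RNA of the melanoma cells.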

Results

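MNT-1, a pigmented human melanoma cell line, was grown for 72 h with HaCaT cells, an immortalised human keratinocyte line that had been infected with lentivirus. The HaCaT cells carried either a non-targeting construct or a knockdown of KRT5, the type II keratin of basal keratinocytes. Cells negative for GFP were then sorted by flow cytometry and their polyadenylated RNA was sequenced. Each of the 2 groups held 3 libraries, numbered 1 to 3. The data comprised 1130 human genes with an unadjusted p below 0.05 in the authors' deposited table (called listed genes here), of which 566 had higher and 564 lower values in the knockdown co-culture. The values of these genes, read counts divided by a size factor and called normalized counts, summed to between 1320190 in control library 2 and 1598603 in knockdown library 1, and the total depth of each library is unknown. With the smallest step of each library assumed to be 1 read, knockdown library 1 stood apart within its group, with a chi-square per degree of freedom of 32.0 against library 2 and 39.4 against library 3. The other pairs within a group lay between 3.56 and 7.80, and no pair was close to sampling noise. The labels do not say whether the libraries came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

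The comparison asks how the RNA of the melanoma cells differed after contact with keratinocytes that had lost KRT5. KRT5 RNA was itself found in the sorted fraction of all 6 libraries and fell 11.8-fold, from 5757 ± 1342 normalized counts beside control keratinocytes to 489 ± 63.5 beside knockdown keratinocytes (SD, n = 3 libraries per group). The knockdown was made in the keratinocytes, so this fall points to keratinocyte RNA in the sorted fraction. Falls of other epithelial genes therefore need not be changes of the melanoma cells. None of the 6 libraries is of MNT-1 cells alone, so KRT5 RNA made by the melanoma cells themselves is not excluded. Along with KRT5 fell KRT4 and KRT13, keratins of stratified mucosal epithelium, the elastase inhibitor PI3, the cornified-envelope precursor SPRR1A and 27 further genes. FABP4, the fatty acid binding protein of adipocytes and macrophages, rose 6.62-fold, from 21.9 ± 7.77 to 145 ± 21.6 normalized counts (SD, n = 3). All 17 listed interferon-stimulated genes had lower values in the knockdown co-culture, and OAS1 and DDX58 among them fell. Of 41 pigmentation genes 3 were listed, and these 3 did not pass the adjusted threshold.

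KRT5 (ENSG00000186081) lies on chromosome 12 from 52514575 to 52520687 on the minus strand (GRCh38 coordinates). Its log2 fold change in the authors' deposited table was -3.56 (adjusted p = 6.53e-111). The 3 knockdown libraries held 538, 417 and 512 normalized counts of KRT5 and the 3 control libraries 7304, 5062 and 4904, in the direction of their labels. KRT4, on the same chromosome from 52806549 to 52814551, went from 470 ± 74.5 to 82.1 ± 21.5 normalized counts (SD, n = 3). KRT13, on chromosome 17 from 41500981 to 41505705, went from 1720 ± 358 to 806 ± 158 (SD, n = 3). The authors' deposited table gave KRT4 a log2 fold change of -2.52 (adjusted p = 3.04e-30) and KRT13 a log2 fold change of -1.09 (adjusted p = 1.35e-07). For FABP4, on chromosome 8 from 81478419 to 81483263, the log2 fold change in the authors' deposited table was 2.73 (adjusted p = 6.27e-15).

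In all, 33 genes passed an adjusted p of 0.05 in the authors' deposited table, 1 higher and 32 lower, and 32 of the 33 were protein coding. The 2 groups of libraries did not overlap for any of the 33, nor for 945 of the 1130 listed genes (83.6%). Chance gives 10% for genes not selected on these libraries, which the listed genes were. The absolute log2 fold change in the authors' deposited table was at least 1 for 22 of them and at least 2 for 11, with a median of 1.28. In the same libraries the listed keratinocyte markers other than KRT5 summed to 65.6% of their control level. These markers were selected on this comparison and all were lower, so the sum can overstate a fall of keratinocyte RNA. Only 5 of the 33 belonged to a gene list fixed beforehand. The other 28 are described by what each is known to do, a grouping made after their values were seen and not tested for enrichment.

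PI3 went from 505 ± 110 to 119 ± 52.5 normalized counts (SD, n = 3). The authors' deposited table gave PI3 a log2 fold change of -2.09 (adjusted p = 1.31e-12). SLPI, the secretory leukocyte proteinase inhibitor, fell from 94.4 ± 25.1 to 33.2 ± 7.31, and SPINK5, an inhibitor of epidermal kallikreins, from 90.8 ± 23.4 to 29.2 ± 7.33 (SD, n = 3). SERPINB1, an inhibitor of neutrophil elastase, fell from 388 ± 108 to 170 ± 13.3, and KLK10, a kallikrein, from 455 ± 98.4 to 269 ± 13.3 (SD, n = 3). Adjusted p-values in the authors' deposited table were 0.00252 for SLPI, 0.00132 for SPINK5, 7.61e-06 for SERPINB1 and 0.00668 for KLK10.

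LCN2, a lipocalin that binds bacterial siderophores, went from 148 ± 35.8 to 33.3 ± 14.6 normalized counts, and the calprotectin subunits S100A9 and S100A8 from 288 ± 105 to 48.2 ± 26.3 and from 64.6 ± 12.1 to 19.5 ± 6.11 (SD, n = 3). Complement C3 went from 314 ± 79.2 to 155 ± 39.6 and the secretoglobin SCGB1A1 from 52.3 ± 17 to 13 ± 4.45 (SD, n = 3). The log2 fold changes in the authors' deposited table were -2.15 for LCN2 (adjusted p = 1.31e-07), -2.58 for S100A9 (adjusted p = 0.00472), -1.73 for S100A8 (adjusted p = 0.00472), -1.02 for C3 (adjusted p = 0.00673) and -2.01 for SCGB1A1 (adjusted p = 0.00676).

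SPRR1A fell from 99.9 ± 44.3 to 12.6 ± 6.68 normalized counts and the membrane mucin MUC16 from 225 ± 56.3 to 57.3 ± 27.2 (SD, n = 3). AQP3, a water and glycerol channel, fell from 1085 ± 254 to 564 ± 47.5, and SCNN1A, the alpha subunit of the epithelial sodium channel, from 127 ± 15.3 to 52.3 ± 7.26 (SD, n = 3). CEACAM5, a cell adhesion glycoprotein, was near the lower end of measurement, at 18.3 ± 6.27 normalized counts against 1.29 ± 1.12 (SD, n = 3), so the size of its fall is poorly fixed. ELF3, an epithelial ETS transcription factor, went from 258 ± 13.5 to 155 ± 9.85, and CRABP2, which carries retinoic acid, from 128 ± 26.7 to 53.2 ± 17.1 (SD, n = 3). Log2 fold changes in the authors' deposited table were -2.98 for SPRR1A (adjusted p = 1.08e-07), -1.97 for MUC16 (adjusted p = 2.36e-07), -0.94 for AQP3 (adjusted p = 6.21e-06), -1.28 for SCNN1A (adjusted p = 4.73e-04), -3.82 for CEACAM5 (adjusted p = 0.0441), -0.73 for ELF3 (adjusted p = 0.00807) and -1.27 for CRABP2 (adjusted p = 0.00785). ADGRF1, an adhesion receptor coupled to G proteins, had 39.0 ± 3.28 against 6.15 ± 2.91 normalized counts (SD, n = 3), few reads as well. The membrane proteins PROM2, MAL2 and ADGRF1 fell, with log2 fold changes of -0.83, -0.74 and -2.66 in the authors' deposited table (adjusted p = 0.0143, 0.0171 and 8.08e-04).

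The enzymes AOC1 (diamine oxidase), ALDH3A1 (an aldehyde dehydrogenase) and GPX2 (a glutathione peroxidase) fell. AOC1 went from 59.1 ± 5.73 to 14.6 ± 3.14 normalized counts, ALDH3A1 from 316 ± 53.1 to 151 ± 18.3 and GPX2 from 318 ± 33.2 to 131 ± 61.1 (SD, n = 3). The authors' deposited table gave log2 fold changes of -2.01 for AOC1 (adjusted p = 3.53e-04), -1.07 for ALDH3A1 (adjusted p = 1.64e-05) and -1.28 for GPX2 (adjusted p = 0.00286). The smallest falls were those of CTLA4, an inhibitory receptor best known from T cells, from 497 ± 24.3 to 339 ± 21.6, NKAIN4, a partner of the sodium pump, from 1058 ± 136 to 735 ± 87.0, and DTX3L, a ubiquitin ligase that works with PARP9, from 1912 ± 23.9 to 1447 ± 124 (SD, n = 3). CICP14, a processed pseudogene whose reads can be shared with near-identical copies, went from 584 ± 30.2 to 391 ± 54.3 (SD, n = 3). Log2 fold changes of these 4 genes in the authors' deposited table were -0.55 for CTLA4 (adjusted p = 0.0171), -0.53 for NKAIN4 (adjusted p = 0.0467), -0.40 for DTX3L (adjusted p = 0.0364) and -0.58 for CICP14 (adjusted p = 0.0213).

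**Figure D1:**
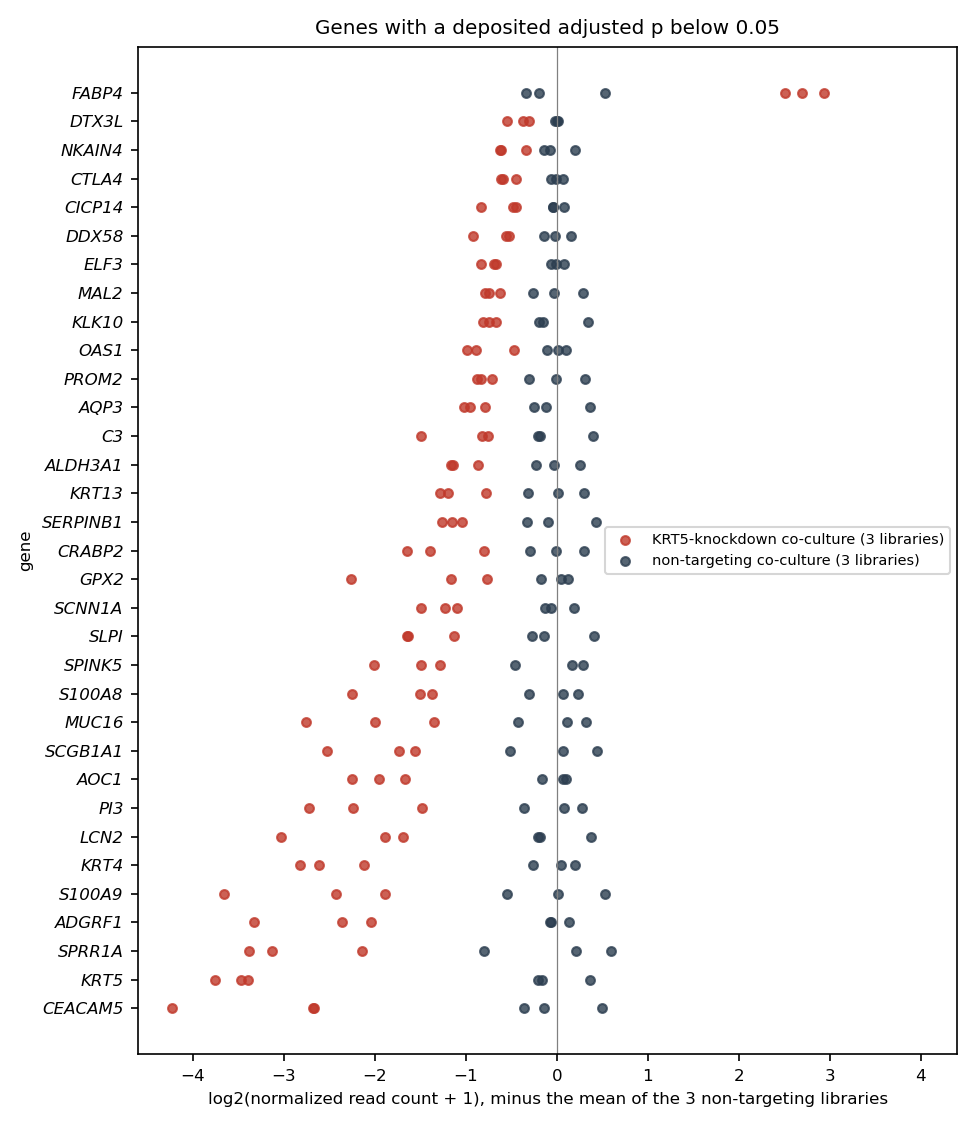
Normalized read counts of the 33 genes with an adjusted p below 0.05 in the authors' deposited table, on the log2(count + 1) scale and relative to the mean of the 3 non-targeting libraries (x axis), with genes on the y axis in order of fold change. Each point is 1 library, and for every gene the 3 knockdown libraries (red) lie on 1 side of the 3 non-targeting libraries (dark blue), above them for FABP4 and below them for the other 32.

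Of 45 keratinocyte markers, 16 were listed, and all 16 had lower values in the knockdown co-culture. KRT5, KRT4 and KRT13 passed the threshold adjusted over all genes, and 8 members passed when adjusted over the list alone. Members that did not pass over all genes included KRT6A at 1830 ± 259 normalized counts in the knockdown against 2480 ± 704 in the control co-culture, KRT7 at 267 ± 21.2 against 412 ± 79.6, the plakophilin PKP1 at 870 ± 86.4 against 1082 ± 177 and the desmosomal cadherin DSC3 at 338 ± 35.1 against 429 ± 67.7 (SD, n = 3). KRT6A shares reads with near-identical keratin genes, so its value is uncertain. The balance of 0 higher and 16 lower differed from that of the other listed genes, 566 higher and 548 lower (two-sided Fisher's exact test, adjusted p = 1.07e-04 over 16 lists). The list did not pass at an absolute log2 fold change of at least 1 (5 members, adjusted p = 1 by the same exact test) or an adjusted p below 0.01 (3 members, adjusted p = 1). In the first setting the other genes were 46 higher and 182 lower, and in the second 1 higher and 21 lower. So few lower members could not pass against them, and neither setting tests the list. Without control library 1, limma gave 6 of the 16 members an unadjusted p below 0.05. Without KRT5, the 15 remaining markers summed to 6317 ± 371 normalized counts in the knockdown co-culture and 9623 ± 2006 in the control co-culture (SD, n = 3), or 65.6% of the control level. These 15 were listed because they differed in this comparison, so the sum can overstate a fall of keratinocyte RNA. Control library 1 was the highest control in 15 of the 16 members. The other 29 markers were not listed, and their levels were not analysed here.

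Of 39 interferon-stimulated genes, 17 were listed and all 17 had lower values in the knockdown co-culture. OAS1, which makes the activator of RNase L, and DDX58, which encodes the RNA sensor RIG-I, passed the threshold adjusted over all genes, and 12 members passed when adjusted over the list alone. OAS1 fell from 672 ± 48.9 to 395 ± 77.4 normalized counts and DDX58 from 424 ± 44.0 to 268 ± 38.7 (SD, n = 3). The authors' deposited table gave log2 fold changes of -0.76 for OAS1 (adjusted p = 7.79e-04) and -0.66 for DDX58 (adjusted p = 0.0198). Members that did not pass over all genes included OAS3 at 5132 ± 259 against 6205 ± 125 and IFIT1 at 187 ± 13.7 against 274 ± 22.9 (SD, n = 3). PARP9 stood at 951 ± 140 against 1305 ± 60.4 (SD, n = 3). Its locus reaches to 122564577 on chromosome 3, and that of DTX3L begins at 122564238 on the other strand. Reads in this short overlap may not be separable where strand was not used. The balance of 0 higher and 17 lower differed from that of the other listed genes, 566 higher and 547 lower (two-sided Fisher's exact test, adjusted p = 1.05e-04 over 16 lists). This list too did not pass at an adjusted p below 0.01 (1 member, adjusted p = 1 by the same exact test), where the other genes were 1 higher and 23 lower. It had 0 members with an absolute log2 fold change of at least 1, so neither setting could test it. Without control library 1, limma gave 11 of the 17 members an unadjusted p below 0.05. Knockdown library 1 was the lowest of its group in 12 of the 17 members, and control library 1 the highest of its group in 11.

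**Figure D2:**
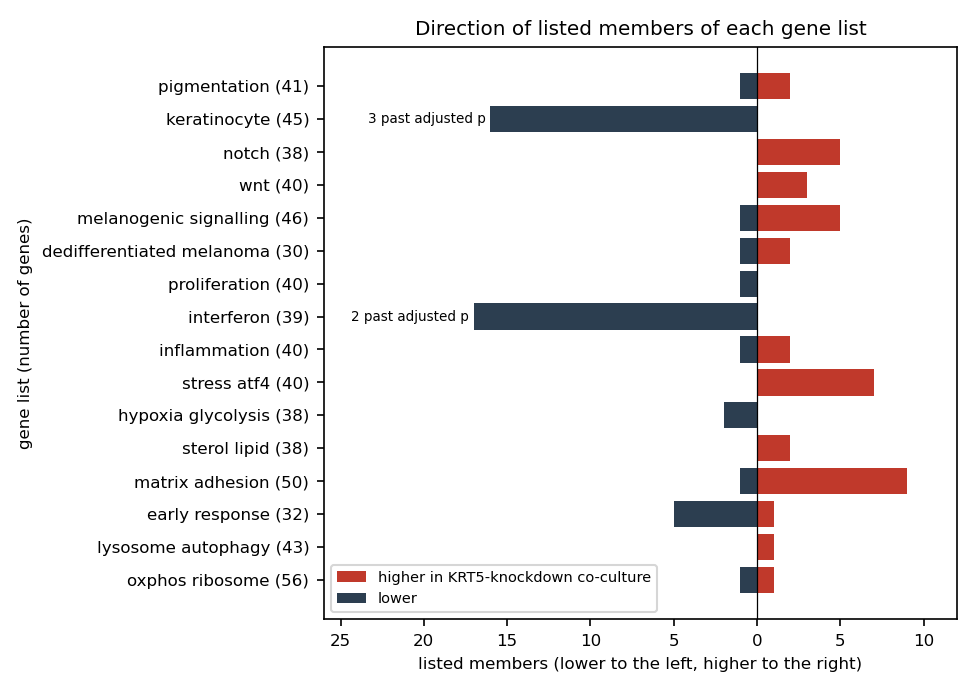
Number of listed genes (unadjusted p below 0.05 in the authors' deposited table) in each of 16 gene lists (y axis, with the number of genes in each list), drawn to the right where values were higher in the knockdown co-culture and to the left where they were lower (x axis, genes). The keratinocyte list, with 16 lower, and the interferon list, with 17 lower, are the only lists whose balance differed from that of the other listed genes, and the labels beside their bars give the members that passed the adjusted threshold.

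Notch pathway, endoplasmic-reticulum stress and matrix genes leaned the other way, without any listed member passing the threshold adjusted over all genes. The 5 listed of 38 Notch genes all had higher values, and 1 of them, the transcriptional repressor HEY1, passed when adjusted over the list alone. HEY1 stood at 2930 ± 521 normalized counts against 2162 ± 33.7, the ligand JAG1 at 2555 ± 206 against 2201 ± 33.1, the ligand DLL3 at 121 ± 19.1 against 81.2 ± 21.4 and the receptor NOTCH3 at 7121 ± 1515 against 5821 ± 384 (SD, n = 3). The 7 listed of 40 amino-acid and endoplasmic-reticulum stress genes, among them the chaperone HSP90B1 and the kinase-like regulator TRIB3, also all had higher values, and 0 passed when adjusted over the list alone. Of 10 listed among 50 matrix and adhesion genes, 9 had higher values, and 0 passed when adjusted over the list alone. Fibrillin FBN1 stood at 52.7 ± 11.1 against 26.2 ± 4.58 and the collagen COL4A2 at 3525 ± 630 against 2826 ± 110, while the hyaluronan receptor CD44 stood at 1646 ± 418 against 2061 ± 38.1 (SD, n = 3). The balance of these lists did not pass Fisher's exact test against the other listed genes (adjusted p = 0.198 for Notch, 0.0818 for stress and 0.0838 for matrix). Knockdown library 1 was the highest of its group in all 5 Notch members, all 7 stress members and 9 of the 10 matrix members.

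**Figure D3:**
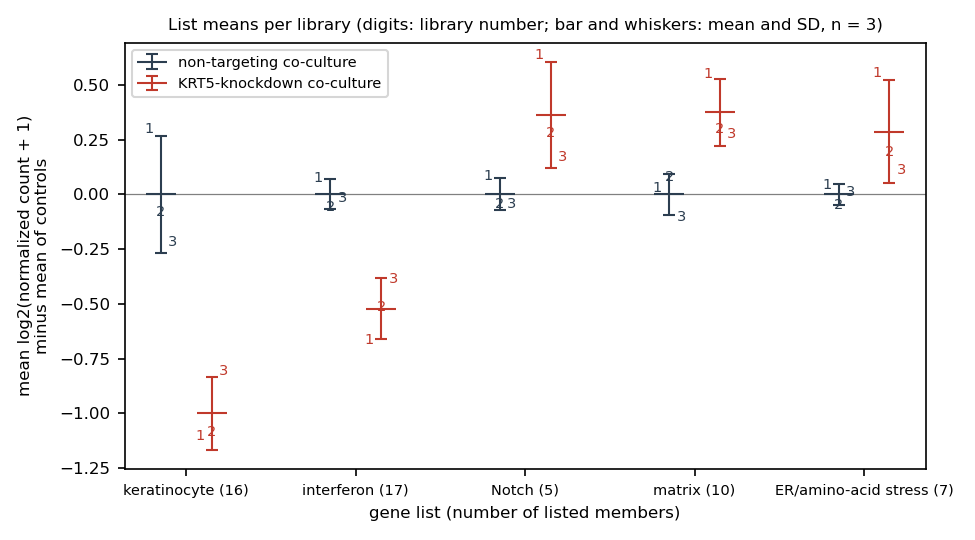
Mean log2(normalized count + 1) over the listed members of 5 gene lists in each library, relative to the mean of the 3 control libraries (y axis, log2 units), with the lists on the x axis. Digits are library numbers, and bars with whiskers are the mean and SD of 3 libraries. The mean difference of the knockdown libraries was -0.999 for the keratinocyte list, which includes KRT5, and -0.52 for the interferon list. Over the 13 keratinocyte members that were not called it was -0.68. For the Notch, matrix and stress lists knockdown library 1 lies highest.

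Of 41 pigmentation genes, 3 were listed, the receptor tyrosine kinase KIT at 6560 ± 149 normalized counts against 5781 ± 353, BLOC1S3, a subunit of a melanosome-biogenesis complex, at 667 ± 97.4 against 538 ± 39.9, and the transcription factor IRF4 at 352 ± 52.8 against 457 ± 91.0 (SD, n = 3). None of the 3 passed when adjusted over all genes, and 0 passed when adjusted over the list alone. The other 38, which include MITF, TYR, TYRP1, DCT and PMEL, were not listed, and their levels were not analysed here. Melanogenic signalling had 6 listed of 46 genes, 5 higher and 1 lower, among them the adenylate cyclases ADCY1 and ADCY6, and 0 passed over all genes or when adjusted over the list alone. The 3 listed of 40 Wnt genes, CTNNB1, LRP6 and FZD7, had higher values, and 0 passed over all genes or when adjusted over the list alone. CTNNB1, which encodes beta-catenin, stood at 21504 ± 879 normalized counts against 18575 ± 377 (SD, n = 3). Of 30 genes of dedifferentiated melanoma, JUN and TWIST1 had higher and CTGF lower values, and 1 of them, JUN, passed when adjusted over the list alone. Fisher's exact test gave these lists adjusted p = 1 for pigmentation, 0.443 for melanogenic signalling, 0.443 for Wnt and 1 for dedifferentiated melanoma.

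The remaining lists had few listed members, and none of these passed over all genes. Early response genes had 6 listed of 32, with JUN higher and EGR2, NR4A3, FOSL2, IER3 and CTGF lower (Fisher's exact test, adjusted p = 0.329). Only 1 passed when adjusted over the list alone, again JUN, which is in both lists. Proliferation had 1 of 40 listed, RRM2, at 915 ± 147 normalized counts against 1144 ± 78.9 (SD, n = 3). Inflammation had 3 of 40, with MMP1 and SOD2 higher and BIRC3 lower. Hypoxia and glycolysis had 2 of 38, ALDOC and NDRG1, both lower, and sterol and lipid synthesis 2 of 38, CYP51A1 and PMVK, both higher. Lysosome and autophagy had 1 of 43, GABARAPL1, and the respiratory chain and ribosome 2 of 56, RPS3 higher and RPL23 lower. In these 6 lists 0 members passed when adjusted over the list alone, and Fisher's exact test gave adjusted p between 0.443 and 1.

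The calls, fold changes and adjusted p-values are those of the authors, whose adjustment covered 16311 genes. A moderated test with limma on the listed genes alone called 3 of the 33, KRT5, KRT4 and FABP4. Without control library 1 that test called 1 gene, KRT5, and without control library 2 or 3 it called 2. Without knockdown library 1 it called 14, of which 11 were among the 33. Its adjusted p-values rest on genes selected on these same libraries, so these counts do not measure how stable the calls are.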

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

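The setting without both libraries numbered 1, the restriction to listed genes with an adjusted p below 1 and the removal of a GC trend were chosen after the data were seen. The 33 calls became 25 at an adjusted p of 0.01, 22 with an absolute log2 fold change of at least 1, 32 and 28 at minimum means of 10 and 50, and 30 without the keratinocyte list. The limma test on the listed genes called 3, also 3 with a pseudocount of 0.5 and 6 with a pseudocount of 5. Leaving out single libraries gave 1 to 14 calls (1 without control library 1, 2 without control library 2 or 3, 7 and 8 without knockdown libraries 2 and 3, 14 without knockdown library 1), and leaving out both libraries numbered 1 gave 19. Not all of these were among the 33, which held 6 of the 7, 7 of the 8, 11 of the 14 and 16 of the 19. Directions of the 33 are no evidence of stability here, since the genes were selected on these libraries and their groups do not overlap. Libraries with the same number did not deviate together (correlations over genes of -0.15, 0.05 and -0.22), and with the replicate block limma called 38 genes, 24 of them shared with the 33. The count of 2 lists with an uneven balance stayed at 2 among listed genes with an adjusted p below 1. It fell to 0 among genes with an absolute log2 fold change of at least 1 and to 0 among genes with an adjusted p below 0.01. There few members are left and most other genes are lower too, so the 2 lists could not pass. Settings without a library or with the block keep the listed genes as they are, so the count there could hardly change. At an unadjusted limma p below 0.05, lower keratinocyte members (16 listed) numbered 6 to 15 when single libraries were left out (6 without control library 1, 9 without knockdown library 2, 10 without knockdown library 1 or control library 2) and 10 without both libraries numbered 1, and lower interferon members (17 listed) numbered 11 to 14 (11 without control library 1). Higher Notch members (5 listed) numbered 3 with limma, with pseudocounts of 0.5 and 5, with the replicate block and without both libraries numbered 1, and 1 to 5 without single libraries (5 without knockdown library 3, 2 without knockdown library 1 or 2 or control library 1, 1 without control library 2 or 3). Higher matrix members (9 listed) numbered 4 with the block, 1 to 8 without single libraries (1 without control library 1, 2 without control library 2 or 3) and 5 without both libraries numbered 1. Higher stress members (7 listed) numbered 3 with limma and with pseudocounts of 0.5 and 5, 2 with the block, 0 to 6 without single libraries (0 without each control library in turn, 2 and 3 without knockdown libraries 1 and 2) and 4 without both libraries numbered 1. Fewer libraries and genes selected on all 6 give part of these losses, and otherwise the cause was not tested. Among the fold changes of single genes under other pseudocounts or without a library, 38 kept their call, 226 kept their direction without passing in limma and 0 reversed, which the non-overlap of the groups made nearly certain. The keratinocyte difference of -0.999 on the log2 scale, over all 16 listed members with KRT5, ranged from -1.11 to -0.85 without single libraries. The median absolute log2 fold change of 1.28 became 1.26 from means with a pseudocount and 1.14 at a minimum mean of 50. Neither edgeR nor DESeq2 was run, with TMM or with DESeq2 size factors, nor was a set test with a preset or estimated correlation, because these need values of all genes.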

Other observations

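The tests of called genes against all listed keratinocyte markers, of genes whose ratio to the reference overlaps and of GC content as the whole cause were chosen after the results they test were seen. Below the adjusted threshold, the following genes were picked after their values were seen. FABP5, which encodes another fatty acid binding protein and lies near FABP4 on chromosome 8, was at 96.2 ± 12.3 normalized counts in the knockdown against 60.3 ± 22.8 in the control co-culture, and the lipoprotein lipase LPL at 321 ± 42.8 against 213 ± 25.2 (SD, n = 3). The vitamin D receptor VDR was at 39.6 ± 3.53 against 78.1 ± 11.9, and SOCS3, a feedback inhibitor of cytokine signalling, at 489 ± 98.1 against 336 ± 27.4 (SD, n = 3). In the authors' deposited table their adjusted p-values were 0.755, 0.185, 0.232 and 0.232. SERF1A, which has a near-identical copy, was at 80.3, 109 and 6.76 normalized counts in the 3 knockdown libraries and at 1.02, 2.12 and 4.86 in the 3 controls.

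The balance of directions depended on the threshold. At an unadjusted p of 0.05 the listed genes were nearly balanced, 566 higher and 564 lower. Those with an adjusted p below 1, which alone could be called, were 544 higher and 479 lower. At an adjusted p of 0.05 they were 1 higher and 32 lower. Among listed genes with a mean over 50 normalized counts, 511 were higher with a median log2 fold change of 0.32 and 366 lower with a median of -0.42. The authors adjusted over 16311 genes, of which 816 would be listed by chance, beside 1023 listed with an adjusted p below 1.

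Of the 32 genes called lower 3 are in the keratinocyte list, and 28 of the 33 called genes are in none of the 16 lists, while a smaller share of keratinocyte RNA in the knockdown libraries is a candidate explanation for the lower values. Leaving out the targeted KRT5, 58.1% of the genes called lower (18 of 31) fell further than a reference of 13 uncalled keratinocyte markers in all 3 knockdown libraries, but a reference without called genes favours such a result. Against the median of all 15 listed markers other than KRT5 it was 64.5% (20 of 31), which has no chance value here because the genes were selected on the same libraries and KRT4 and KRT13 are also among the 15, and which a smaller amount of keratinocyte RNA alone could reach if the melanoma cells express much of these markers themselves. That condition was not tested beyond control library 1 and keeps the explanation open. In control library 1 the 13 uncalled markers were 1.33-fold higher at the median than in the other controls, beside 1.47-fold for KRT5. The markers thus followed KRT5 only in part there, and 1 library cannot decide the condition. In that library the 31 genes called lower other than KRT5 were 1.23-fold higher at the median. For the 13 called genes whose ratio to the uncalled markers overlapped between the groups (median -0.051, SD 0.20), a change in share cannot be told apart from a change in the cells, and for all 32 the share of values moving with the reference within groups, 72.9%, left open whether the keratinocytes or the melanoma cells changed.

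The lower interferon-stimulated genes may come from the melanoma cells or from keratinocyte RNA carried through the sort. Within groups their mean correlation with the keratinocyte reference was 0.39 (SD 0.47 over 17 genes, 6 libraries), between the values set for either reading, so the sources cannot be told apart by this test. In control library 1, where the keratinocyte reference was 1.33-fold higher than in the other controls, the interferon genes were 1.05-fold higher at the median. The knockdown libraries gave the opposite picture, with reference means of 7.47, 7.57 and 7.84 beside interferon means of 8.42, 8.56 and 8.69 for libraries 1, 2 and 3, the same order in both. A response of the melanoma cells to KRT5-depleted neighbours stays open and untested.

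Knockdown library 1 was the highest of its group in 84.3% of the 510 listed higher genes with a GC value and a mean of at least 50 normalized counts, and the lowest in 68.3% of the 366 lower ones, so listed genes of both directions may lean on this library. Its deviation rose with GC content over genes (Spearman's rho 0.31), but library 2 of the same group gave -0.31, deviations within a group depend on each other, and a GC bias of library 1 cannot be told apart from a bias of the others. For gene length rho was -0.15, with -0.25 in control library 1, which leaves it open as well. After the GC trend was removed, library 1 was still highest in 69.2% of the higher genes and lowest in 80.6% of the lower ones. The genes were selected on group means that include library 1, so the share to expect without a GC effect is unknown. GC content as the whole cause therefore stays open. With the trend removed, the median log2 difference of the higher genes went from 0.31 to 0.26, beside 0.20 without library 1. No batch is given in the labels, and a biological difference of this culture was not tested.

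Among the 10 ways to split the 6 libraries 3 against 3, 2 gave at least 3 genes at an adjusted limma p below 0.05, with 3 in the real split and 3 as the highest of the others. At an unadjusted p below 0.05 the real split gave 848 listed genes and the highest other 60, in genes selected on the real split. With 10 splits no share under 0.05 can be reached.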
